A study of Mus musculus with 6 samples.

How the data were processed

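Total RNA of embryonic mouse pancreata was sequenced from 3 control samples and 3 samples treated with AMI-5 at 10 µM, and each sample gave 1 library. Values used were read counts per gene as deposited, not normalized, in 1 table of 49763 entries whose columns match the marks in the sample titles. Per the submitters' processing notes, bcl2fastq 2.19.1, GSNAP 2018-05-30 and featureCounts 1.6.2 were used with mouse genome build mm10, and the deposited table names Ensembl release 87 as its annotation. The deposited gene length column, in bases of merged exons, entered only the length trend. The strand setting of the counting, the treatment of reads that map to several places and the read length are not given in the sources used here. The libraries were strand specific per the labels, which name 2 versions of the same kit, an earlier one for samples marked A. Growth and treatment steps are referred by the labels to publications not used here.

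The 92 spike-in sequences of the table held 1 read over the 6 libraries and were left out, which left 49671 genes. Symbols, classes, GC content and shared sequence came from the GENCODE M21 annotation of mm10, which placed 99.81% of the shared gene identifiers at an overlapping position. A symbol was found for 49326 genes. Shared sequence of a gene is the percent of its exonic 50-mers found in another annotated gene, with 25-mers as a shorter alternative.

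Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust dispersion, robust quasi-likelihood fit and F test, two-sided), with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as threshold. The filter left 17519 genes, and the common biological coefficient of variation was 9.65%. Log2 fold changes are AMI-5 over control and SE is their standard error. CPM, the read counts scaled by edgeR to a common TMM-adjusted library size, is given as mean ± SD of 3 libraries. Depth limits precision most in the controls, with 12445425 to 13321899 counts per library against 22894312 to 24805188 with AMI-5. Where a group had 1 to 3 reads of a gene in all, the ratio of rates is given with a 95% exact binomial (Clopper-Pearson) interval, which covers counting error only. Technical measures per library were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

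There were 37 gene lists, for endocrine progenitors, pan-endocrine genes, beta cells, other endocrine cells, acinar cells, ducts and trunk, multipotent progenitors, mesenchyme, mesothelium, endothelium, erythroid cells, leukocytes, neural cells, spleen primordium, gut and liver, mitosis, DNA replication, arginine methyltransferases, lysine methyltransferases, retinoid genes, the Notch pathway, targets of Yap, Wnt, FGF and ERK, p53 and Nrf2, the integrated stress response, endoplasmic reticulum chaperones, heat shock, hypoxia and glycolysis, cholesterol, interferon, immediate early genes, mitochondrial mRNAs, histone cluster genes, ribosomal proteins and small noncoding RNAs. Each list was tested against the other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry, which asks whether the genes of a list move one way on balance.

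Genes are named by a rule with 3 parts. The first takes 13 genes of the study's question (Aldh1b1, Neurog3, Ins1, Ins2, Gcg, Cpa1, Ptf1a, Pdx1, Nkx6-1, Sox9, Prmt1, Prmt5 and Carm1). The second takes the 12 protein-coding genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes named Gm with digits or ending in Rik. The third takes, from each list described, up to 4 members past the threshold with the smallest p and up to 2 with the largest mean. Because the second part selected many genes with near copies, it was repeated over unique-sequence protein-coding genes (under 5% of 50-mers shared), a step chosen after seeing the data. Some genes that the rule takes are not reported here. Nr5a2, Gapdh, Isg15 and Irf7 are named outside the rule, after their values were seen. The arginine methyltransferase list also holds partners of these enzymes.

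On simulated counts for the 17519 genes of the AMI-5 against control comparison with 200 genes changed, the test recovered 43.9%, 83.3% and 95.5% of genes changed by a log2 fold change of 0.5, 1 and 2, and 8.12% of its calls were false. With a simulated GC trend, 7715 genes were called before and 10 after trend removal. That trend was linear and came without a length trend or changed genes, so it does not show how well removal works on these data. Libraries of a group differed by more than counting noise (chi-square per degree of freedom of 6.94 to 18 over the 6 pairs), a spread that may be technical. Each library was counted as 1 sample.

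Alternatives fixed in advance were RLE, upper-quartile and totals-only scaling, library sizes without the 50 most abundant genes, DESeq2 1.42.0, limma voom, no filter, a stricter filter (at least 5 CPM in at least 3 libraries), the replicate number as a block, removal of GC and length trends per library by smooth offsets (mgcv 1.9.3) with and without the block, a test against a fold of 1.5, and leaving out each library. Fits on unique-sequence genes, with and without trend removal, and on AMI-5 libraries thinned to the mean control depth, as well as list tests with both trend removal and an estimated correlation, were chosen after seeing the data.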

Results

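RNA was sequenced from embryonic mouse pancreata (14.5 dpc, strain C57BL/6J), either controls or treated with AMI-5 at 10 µM. AMI-5 is a small-molecule inhibitor of protein methyltransferases, arginine methyltransferases among them. The comparison addressed the effect of the compound on differentiation of the pancreas, a tissue in which multipotent progenitors give rise to acinar, ductal and endocrine cells. There were 3 control and 3 AMI-5 libraries. Gene counts summed to 12445425, 12836163 and 13321899 in the control libraries and to 22894312, 23075830 and 24805188 in the AMI-5 libraries, so that low genes were measured more precisely after AMI-5. Nothing in the labels says that the samples of a group came from separate cultures or animals, and p-values therefore measure only the spread between these samples, which may be technical. Per the labels, samples marked A were prepared with an earlier version of the library kit than the others, and the control titles carry the mark A while the AMI-5 titles carry the mark Am. Read literally, kit and treatment coincide, and a difference between the groups cannot be told apart from a difference between kits.

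In the AMI-5 libraries, genes of digestive enzymes, glycolysis and the amino acid stress response were higher, and genes of endocrine progenitors, cell division and cholesterol synthesis were lower. Of 17519 genes tested, 4820 were higher and 4652 lower with AMI-5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2340 and 392 of these had an absolute log2 fold change of at least 1. Higher genes made up 50.9% of the calls, against 57.5% with no filter, 57% with upper-quartile scaling, 40.2% with libraries scaled by their totals alone (3962 higher and 5883 lower) and 38.6% with trends in GC content and length removed over all genes (3551 higher and 5651 lower). That trend removal kept 2759 of 4802 higher and 3167 of 4646 lower calls. Processed pseudogenes made up much of the larger rises: 1576 of the 1679 that passed the filter were higher. A gene near 0 in controls can pass the filter through its AMI-5 counts, so this share holds for tested pseudogenes only. The trends removed over all genes were fitted with these included, so values after that removal may carry part of their rise. The fit over unique-sequence genes leaves them out. Protein-coding genes with under 5% of their 50-base sequences (50-mers) in another annotated gene are called unique-sequence genes here. Of these 10915 genes, 2143 were higher and 3308 lower in the fit over all genes. Fitted alone, 2495 were higher and 2733 lower. This class was chosen after seeing the data, whereas the gene lists, the edgeR and camera tests reported first and the rule for named genes over all protein-coding genes were fixed before the data were examined. Of the 37 gene lists, 4 shifted up and 7 shifted down relative to other genes (camera with a preset inter-gene correlation, adjusted p under 0.05). None of these calls held with an estimated correlation (adjusted p of 0.789 to 0.987 over the lists), and the preset test also called 10 to 20 lists in the 9 other splits of the 6 libraries. Those splits mix both groups on each side, so that part of the difference between the groups may remain in their calls. The genes that lists were tested against included the processed pseudogenes, most of them higher. Fitted over unique-sequence genes alone, leukocyte (camera adjusted p = 0.0019) and gut and liver genes (0.0195) gained a call up. Genes of other endocrine cells (0.0389) and Notch genes (0.0324) gained a call down. None of the gained calls held with an estimated correlation (adjusted p of 0.543 to 0.612). Where a count adjusted over the list alone differed from the count over all genes tested, it is given beside it.

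Genes of acinar cells, which make and secrete digestive enzymes, were mostly higher with AMI-5. Of 33 acinar genes tested, 26 were higher and 1 was lower, with a median log2 fold change of 1.61 (camera adjusted p = 8.67e-07, and adjusted p = 0.789 with an estimated correlation). Gp2, the main glycoprotein of zymogen granule membranes (ENSMUSG00000030954, chromosome 7, 119442537 to 119459285, mm10), went from 8.62 ± 4.36 to 201 ± 87.5 CPM (SD, n = 3 in each group), a log2 fold change of 4.55 (SE 0.60, adjusted p = 0.00372). Zg16, a zymogen granule lectin, rose from 2.63 ± 1.30 to 49.3 ± 5.98 CPM, the chymotrypsin-like protease Ctrl from 8.08 ± 5.13 to 134 ± 22.9 CPM, and Cuzd1, a zymogen granule protein, from 12.9 ± 4.96 to 141 ± 11.02 CPM (SD, n = 3). The lipase relative Pnliprp1 rose from 16280 ± 3873 to 48091 ± 4307 CPM, a log2 fold change of 1.56 (SE 0.19). Chymotrypsinogen Ctrb1 rose from 38028 ± 5869 to 69772 ± 9357 CPM, a log2 fold change of 0.88 (SE 0.13). Removing trends with GC content and length over all genes turned the value of Ctrb1 to -0.46, and removing them over unique-sequence genes gave 1.05. The former also lowered the log2 fold change of Zg16 from 4.22 to 3.34 and of Ctrl from 4.04 to 3.20. The trypsinogens Prss2 and Try5 and the amylases Amy2a5 and Amy1 had the smallest p-values of the list (log2 fold changes of 3.56, 2.69, 7.68 and 1.43), but share 7.83%, 47.6%, 53.5% and 33.3% of their 50-mers with other genes, so these values are uncertain. Prss2 and Try5 were at 1.80 and 1.13 after trend removal. Among the 22 unique-sequence members, 17 were higher and 1 lower, with a median log2 fold change of 1.17. Trend removal left 17 higher and 6 lower genes over the whole list, and over unique-sequence genes 15 higher and 1 lower of 22. Acinar list genes together took 7.99% ± 1.28 of counts in controls and 17.04% ± 1.63 with AMI-5 (SD, n = 3).

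Some acinar genes rose little or did not rise. Ptf1a, a transcription factor that pancreas formation and acinar fate require (chromosome 2, 19445663 to 19447501, mm10), was at 74.5 ± 12.7 CPM in controls and 70.1 ± 2.49 CPM with AMI-5 (log2 fold change -0.087, SE 0.11, adjusted p = 0.530), and 35.4% of its 50-mers lie in another annotated gene. It was lower with GC and length trends removed, at -0.39 (adjusted p = 0.0179). Without control replicate 3 its log2 fold change was -0.22 (adjusted p = 0.0206). Cpa1, a carboxypeptidase that also marks early tip progenitors, was at 6517 ± 1008 and 8207 ± 824 CPM (log2 fold change 0.33, SE 0.12, adjusted p = 0.0403). That call ended in 9 of 21 alternatives. Among these were the fits without control replicate 1 (0.37), control replicate 3 (0.21), AMI-5 replicate 1 (0.31) or AMI-5 replicate 3 (0.30), and with GC and length trends removed over all genes (0.064), but not over unique-sequence genes (0.36, adjusted p = 0.0425). The lower member, named after its value was seen, was Nr5a2, a nuclear receptor of acinar cells (log2 fold change -0.40).

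**Figure D1:**
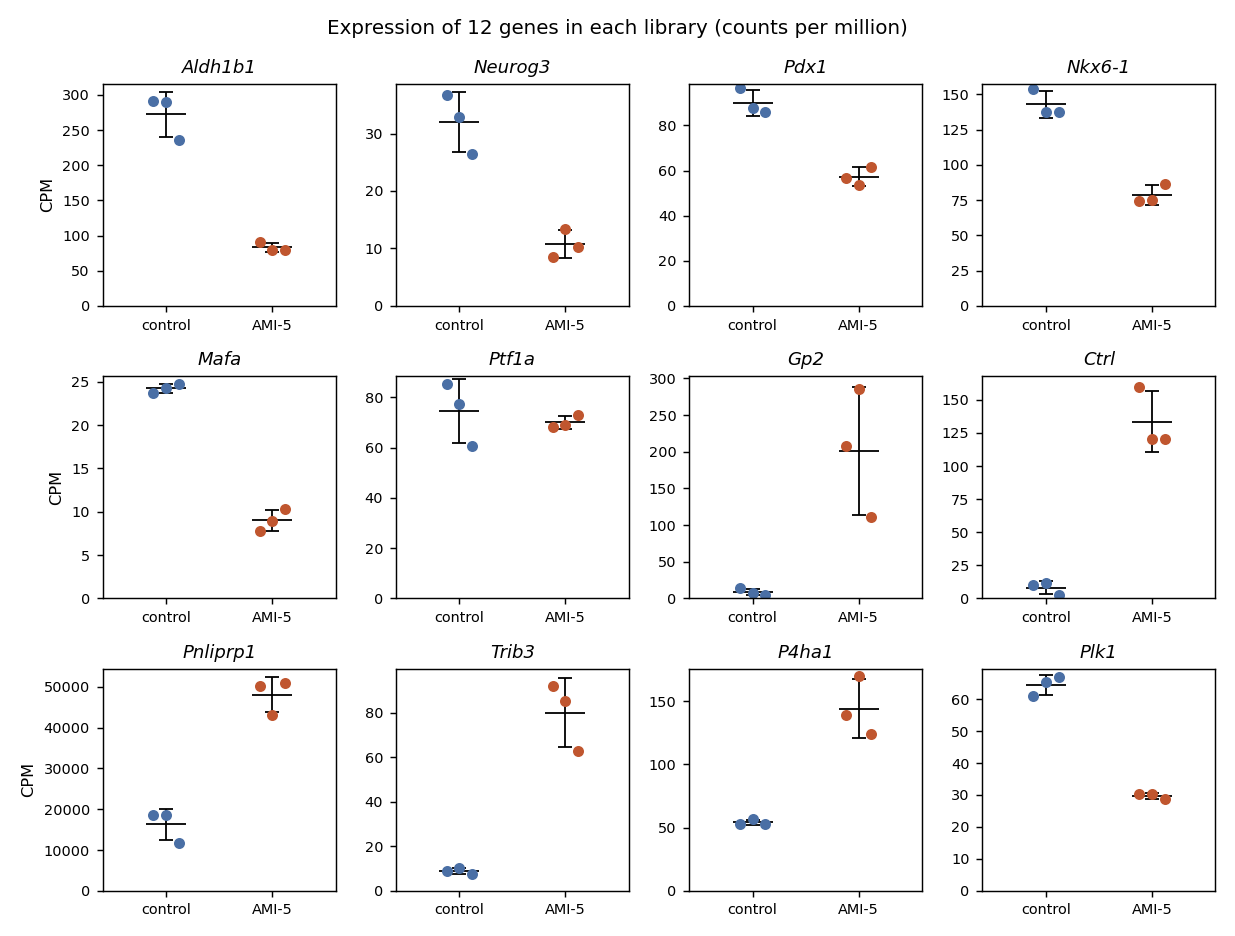
CPM (y axis) of 12 genes in each of the 6 libraries by group (x axis). Points are libraries and bars the group mean ± SD (n = 3). Mean values went from 8.62 to 201 CPM for Gp2, from 273 to 83.3 CPM for Aldh1b1 and from 74.5 to 70.1 CPM for Ptf1a.

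Endocrine progenitor genes were lower. Of 19 tested, 13 were lower and 0 higher, with a median log2 fold change of -0.53 (camera adjusted p = 0.00465, and adjusted p = 0.789 with an estimated correlation). Neurog3, the transcription factor that starts the endocrine programme (ENSMUSG00000044312, chromosome 10, 62133090 to 62134763, mm10), went from 32.04 ± 5.20 to 10.8 ± 2.47 CPM, a log2 fold change of -1.57 (SE 0.18, adjusted p = 0.000121), and shares 13.3% of its 50-mers with another gene. The transcription factors Fev, Hes6 and Insm1 had log2 fold changes of -1.10, -0.84 and -0.75. With GC and length trends removed over all genes, Insm1 was at -0.14 and no longer passed the test (-0.33 over unique-sequence genes, adjusted p = 0.00954), Hes6 was at -0.56, and the list as a whole had a median of -0.37 (1 higher and 13 lower) and a camera adjusted p of 0.0733. Over unique-sequence genes with the trends removed, 0 higher and 10 lower of 13 gave a median of -0.61 (camera adjusted p = 0.00124, and adjusted p = 0.384 with an estimated correlation). Among the 13 unique-sequence members, 10 were lower.

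Hormone genes gave a mixed picture that depended mainly on whether GC and length trends were removed over all genes. That removal was fitted with the processed pseudogenes included. Removal over unique-sequence genes, which leaves them out, kept the signs that Ins1, Ins2 and Gcg had before it. Ins2 was at 1919 ± 111 CPM in controls and 1850.3 ± 285 CPM with AMI-5 (log2 fold change -0.053, SE 0.10, adjusted p = 0.686), but at -0.74 and past the test with GC and length trends removed over all genes, and at -0.014 over unique-sequence genes (adjusted p = 0.919). Glucagon, Gcg, was at 774 ± 168 and 1038 ± 181 CPM (log2 fold change 0.42, SE 0.21, adjusted p = 0.159), but passed with limma voom, and was at -0.40 with the trends removed over all genes (adjusted p = 0.198) and 0.19 over unique-sequence genes (adjusted p = 0.549). Ins1 was higher by a log2 fold change of 0.49 (SE 0.094, adjusted p = 0.00127), but removal of GC and length trends turned it to -0.93 over all genes, against 0.39 over unique-sequence genes. Of 20 beta cell genes, 7 were higher and 7 lower, and the list was not called (camera adjusted p = 0.273, and adjusted p = 0.869 with an estimated correlation). With GC and length trends removed over all genes, 2 were higher and 12 lower (camera adjusted p = 0.00436, and adjusted p = 0.886 with an estimated correlation). Over unique-sequence genes, 3 were higher and 8 lower of 19 (camera adjusted p = 0.261). Lower members included the transcription factors Mafa, from 24.3 ± 0.537 to 9.01 ± 1.23 CPM (log2 fold change -1.43), and Nkx6-1, from 143 ± 9.27 to 78.5 ± 6.89 CPM (-0.86, or -0.50 after trend removal), as well as Npy (-1.21, or -3.74 after trend removal over all genes and -1.17 over unique-sequence genes). Of 15 genes of other endocrine cells, 1 was higher and 8 were lower, with the peptide hormone gene Pyy at -0.73 (after trend removal -2.85 over all genes and -0.59 over unique-sequence genes) and the amino acid transporter Slc38a5 at -1.002. That list was not called either (camera adjusted p = 0.0616, and adjusted p = 0.789 with an estimated correlation). Trend removal over all genes gave 1 higher and 10 lower (camera adjusted p = 1.11e-08, and adjusted p = 0.236 with an estimated correlation), and over unique-sequence genes 2 higher and 5 lower of 13 (camera adjusted p = 0.0243, and adjusted p = 0.482 with an estimated correlation). Of 20 pan-endocrine genes, 3 were higher and 6 lower, or 1 higher and 14 lower with the trends removed over all genes and 3 higher and 4 lower of 19 over unique-sequence genes.

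Aldh1b1, an aldehyde dehydrogenase of pancreatic progenitors (ENSMUSG00000035561, chromosome 4, 45799022 to 45804604, mm10), went from 273 ± 32.1 to 83.3 ± 6.66 CPM, a log2 fold change of -1.71 (SE 0.092, adjusted p = 9.67e-08). None of its 50-mers lies in another annotated gene. Of 20 genes of multipotent progenitors, 14 were lower and 2 higher, with a median log2 fold change of -0.31 (camera adjusted p = 0.0154, and adjusted p = 0.789 with an estimated correlation). That list call also ended with GC and length trends removed over all genes, at a median of -0.27 with 1 higher and 12 lower (adjusted p = 0.154), but not over unique-sequence genes, at a median of -0.22 with 1 higher and 9 lower of 16 (adjusted p = 0.000756, and adjusted p = 0.482 with an estimated correlation). Pdx1, a transcription factor of the early pancreas and of beta cells, went from 89.95 ± 5.66 to 57.3 ± 4.10 CPM (log2 fold change -0.65, adjusted p = 1.01e-05). Rbpj, the effector of Notch signalling, was higher (log2 fold change 1.26), with 10.6% of its 50-mers shared. Sox9, a factor of progenitors and ducts, had a log2 fold change of -0.15 (SE 0.058, adjusted p = 0.0491). The call ended in 14 of 21 alternatives, among them without control replicate 1 (-0.11), control replicate 2 (-0.16), AMI-5 replicate 1 (-0.10), AMI-5 replicate 2 (-0.14) or AMI-5 replicate 3 (-0.15). Of 22 ductal and trunk genes, 3 were higher and 10 lower.

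Among Notch pathway genes, 12 of 17 were lower (13 adjusted over the list alone) and 2 higher. The target Heyl had a log2 fold change of -0.87, the target Hes1 of -0.32 and the ligand Dll1 of -1.03. Of 10 Wnt targets, 6 were lower and 1 was higher, with the transcription factor Lef1 at -1.90, Axin2, a feedback inhibitor of the pathway, at -0.84, Nkd1 at -0.79 and Rnf43 at -0.52. Neither list was called (camera adjusted p = 0.0627 for Notch and 0.101 for Wnt, and adjusted p = 0.789 for both with an estimated correlation). After removal of GC and length trends, 3 Wnt targets were lower, Rnf43 was at -0.18 and no longer passed (adjusted p = 0.0611, against -0.27 and adjusted p = 0.0178 over unique-sequence genes), Hes1 was at -0.55, and the Notch list had 4 higher and 8 lower.

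Genes of cell division were lower. Of 20 mitosis genes, 19 were lower and 0 higher, with a median log2 fold change of -0.59 (camera adjusted p = 1.34e-06, and adjusted p = 0.789 with an estimated correlation). Of 22 DNA replication genes, 21 were lower and 0 higher, with a median of -0.60 (camera adjusted p = 4.93e-06, and adjusted p = 0.789 with an estimated correlation). The mitotic kinase Plk1 went from 64.5 ± 3.12 to 29.8 ± 0.920 CPM (log2 fold change -1.11, SE 0.063) and Cdc20, an activator of the anaphase-promoting complex, from 91.1 ± 1.52 to 41.98 ± 3.71 CPM. The spindle checkpoint kinase Bub1b had a log2 fold change of -0.94, the topoisomerase Top2a of -0.65 and the proliferation marker Mki67 of -0.43. Among replication genes, the thymidylate synthase Tyms was at -1.01, the helicase subunit Mcm7 at -1.04 and the ribonucleotide reductase subunit Rrm2 at -0.83. Among unique-sequence members, 13 of 14 mitosis genes and 13 of 14 replication genes were lower.

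Genes of glycolysis and of the response to low oxygen were higher. Of 26 tested, 22 were higher (23 adjusted over the list alone) and 1 was lower, with a median log2 fold change of 0.98 (camera adjusted p = 0.000183, and adjusted p = 0.789 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, went from 54.1 ± 2.23 to 144 ± 23.5 CPM (log2 fold change 1.41, SE 0.11), and the phosphofructokinase Pfkl from 165 ± 5.09 to 253 ± 22.6 CPM (0.62). The glycolytic enzymes Pgk1, Eno1, Ldha and Aldoa had log2 fold changes of 1.72, 0.97, 0.48 and 0.48 (0.75 for Aldoa after trend removal), with 53.9%, 25.99%, 9.26% and 6.43% of their 50-mers in other genes. The lower member, named after its value was seen, was Gapdh (-0.88), which shares 25.1%. Among the 16 unique-sequence members, 13 were higher and 0 lower, with a median of 0.82.

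The integrated stress response, which cells mount on amino acid shortage and unfolded protein, was also higher. Of 17 genes, 14 were higher and 3 lower, with a median log2 fold change of 0.80 (camera adjusted p = 0.00465, and adjusted p = 0.789 with an estimated correlation). Trib3, a pseudokinase induced by this response, went from 8.92 ± 1.54 to 79.96 ± 15.3 CPM, a log2 fold change of 3.16 (SE 0.20, adjusted p = 1.86e-05). The transcription factors Ddit3 and Atf5 had log2 fold changes of 1.51 (0.92 after trend removal) and 1.03, the mitochondrial folate enzyme Aldh1l2 of 1.92 and the stress protein Nupr1 of 1.11. Ddit4, an inhibitor of mTOR signalling, was lower (-0.57). Of 14 endoplasmic reticulum chaperones, 5 were higher and 4 lower, and of 10 heat shock genes 0 were higher and 5 lower (4 adjusted over the list alone).

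Cholesterol synthesis genes were lower. Of 21 genes, 16 were lower and 1 was higher, with a median log2 fold change of -0.41 (camera adjusted p = 0.00465, and adjusted p = 0.794 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, had a log2 fold change of -0.83, and Srebf2, the transcription factor that controls these genes, of -0.58 (-0.20 after trend removal over all genes and -0.31 over unique-sequence genes).

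Arginine methyltransferases are the enzyme class that includes targets of AMI-5. Of 11 genes of these enzymes and their partners, 3 were lower and 1 was higher (0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.335, and adjusted p = 0.794 with an estimated correlation). Of all genes tested, 26.6% were lower. Prmt1 went from 259 ± 11.9 to 166 ± 11.5 CPM (log2 fold change -0.64, SE 0.064, adjusted p = 5.43e-06), Prmt5 from 76.5 ± 1.18 to 61.1 ± 0.256 CPM (-0.32) and Carm1 from 125 ± 8.19 to 93.8 ± 1.63 CPM (-0.42). Carm1 was at -0.068 with GC and length trends removed (adjusted p = 0.341). Of 25 lysine methyltransferase genes, 11 were lower and 1 was higher, with a median log2 fold change of -0.21 (camera adjusted p = 0.025, and adjusted p = 0.789 with an estimated correlation). Kmt5c, Suv39h1 and Dot1l were at -0.85 (-0.37 after trend removal), -0.57 and -0.53. Ehmt2 was at -0.49, but at 0.12 with GC and length trends removed over all genes (-0.090 over unique-sequence genes), which also ended the call of the list (median -0.15, adjusted p = 0.67) and of Dot1l (-0.11). Over unique-sequence genes Dot1l stayed called (-0.24, adjusted p = 0.00444).

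**Figure D2:**
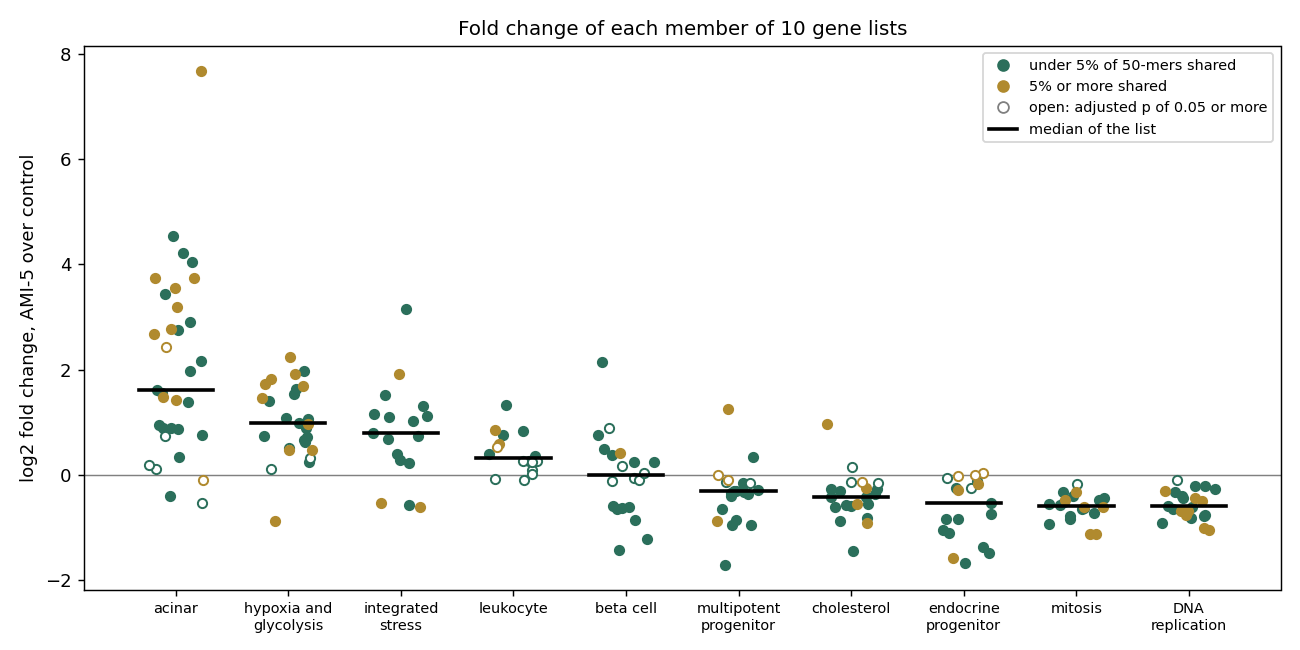
Log2 fold change of AMI-5 over control (y axis) of each tested member of 10 gene lists (x axis). Filled points passed the test and open points did not, green marks members with under 5% of their 50-mers shared and ochre the others, and black bars are list medians, which ran from -0.60 for DNA replication to 1.61 for acinar genes.

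Markers of other cell types moved as well. Of 16 leukocyte genes, 8 were higher and 0 lower, but with GC and length trends removed over all genes 6 higher and 5 lower, and over unique-sequence genes 9 higher and 0 lower of 13. The macrophage receptor Mrc1 went from 21.04 ± 1.36 to 53.2 ± 7.70 CPM (log2 fold change 1.34), and Adgre1 and Ptprc were at 0.84 and 0.76 (0.44 for Ptprc after trend removal), whereas Lyz2 moved from 0.85 to -0.12 with GC and length trends removed. Of 24 mesenchyme genes, 9 were higher and 8 lower (after trend removal 8 higher and 4 lower, and over unique-sequence genes 6 higher and 3 lower of 22), and of 9 mesothelium genes 3 were higher (2 adjusted over the list alone) and 0 lower. Of 16 endothelial genes, 5 were lower (4 adjusted over the list alone) and 0 higher. Of 20 neural genes, 2 were higher and 9 lower, and of 3 spleen primordium genes 2 were lower. Of 10 gut and liver genes, 2 were higher (1 adjusted over the list alone) and 0 lower. The liver transcripts Alb and Afp did not pass the test. They were at 596 and 619 CPM in AMI-5 replicate 2 and at no more than 17.6 and 29.8 CPM in the other libraries. Of 9 erythroid genes, 5 were higher and 2 lower. The embryonic globin Hba-x was at -2.41 (-3.69 after trend removal), while the adult globins Hba-a1, Hbb-bs and Hbb-bt were at 3.13, 3.47 and 4.38 and share 72.3%, 53.2% and 58.3% of their 50-mers. A further adult globin, Hba-a2, was at 5.45 with 89.3% shared, and stayed called after trend removal (3.45, adjusted p = 0.0263) and in every other alternative that tested it. Calls of the former adult globins ended with GC and length trends removed (1.58, 1.504 and 2.20, adjusted p of 0.129, 0.177 and 0.111) and without control replicate 1 (2.99, 3.34 and 4.30). Those of Hba-a1 and Hbb-bs also ended without control replicate 2 (2.87 and 3.37), and that of Hbb-bs without control replicate 3 (3.71). Leaving out AMI-5 replicate 2 gave 2.76 for Hbb-bs and 3.72 for Hbb-bt.

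In other signalling and stress lists, calls went in both directions or were few. Of 17 retinoid genes, 3 were higher and 5 lower (4 adjusted over the list alone). Of 18 Yap targets 5 were higher and 6 lower, and of 11 targets of FGF and ERK signalling 2 were higher and 1 was lower (0 adjusted over the list alone). Among p53 targets, 6 of 19 were higher and 4 lower, among Nrf2 targets 3 of 16 were higher and 6 lower, and among immediate early genes 4 of 19 were higher and 2 lower. Trend removal over all genes changed these counts: Yap targets had 8 higher and 1 lower, retinoid genes 6 higher and 3 lower and p53 targets 4 higher and 6 lower. Over unique-sequence genes it gave 3 and 1, 5 and 2, and 4 and 2, of 16 each. The immediate early list had a median of 0.45 and was not called (camera adjusted p = 0.956). With trends removed over unique-sequence genes it was called up, with 4 higher and 1 lower of 16 (camera adjusted p = 0.00991, and adjusted p = 0.843 with an estimated correlation). No interferon-induced gene of 20 passed with edgeR before trend removal, where 0 had an unadjusted p under 0.05, or with DESeq2, likewise 0. With limma voom 1, Lgals3bp, passed (-0.56, adjusted p = 0.0493), and with GC and length trends removed 2 were lower with edgeR, Bst2 among them (-2.48, adjusted p = 0.0476, against -1.10 before removal and -0.14 without control replicate 1). Control replicate 1 stood apart in this list, with Isg15 at 89.4 CPM and Irf7 at 102 CPM against at most 16.4 and 22.5 CPM in the other libraries. Median, mean and camera direction differed in sign for the pan-endocrine, mesenchyme, ribosomal protein, Yap, FGF and ERK, p53 and chaperone lists, and none of these was among the calls counted at first.

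Over unique-sequence genes, the rule took 24 genes, 12 that rose and 12 that fell, and 24 of them also passed in the same direction with GC and length trends removed over unique-sequence genes. Beside Gp2, Zg16, Ctrl, Cuzd1 and Trib3, the rises were F13a1, a coagulation factor subunit of macrophages (from 2.74 ± 0.243 to 50.2 ± 17.3 CPM, log2 fold change 4.19), the arginase Arg1 (from 3.74 ± 0.410 to 33.1 ± 8.03 CPM, 3.14), the trefoil peptide Tff2 (3.35), Dmbt1 (3.11), the lipase relative Pnliprp2 (2.92) and the cholesterol acyltransferase Soat2 (2.91). Aldoart2, an aldolase-like gene, had 3 reads in the controls and 1273 with AMI-5, a ratio of rates of 247 (95% exact interval 84.3 to 1200, counting error only). It shares 15.7% of its 25-mers though 0.31% of its 50-mers, and its value is uncertain. The falls were led by the cartilage proteoglycan Acan (from 14.3 ± 2.00 to 2.35 ± 0.564 CPM, -2.61) and the endothelial clotting factor Vwf (from 10.97 ± 1.68 to 1.97 ± 0.732 CPM, -2.47). The endothelial lipase Lipg was at -1.96, the cartilage collagen Col2a1 at -1.77, and Id3 and Id1, inhibitors of helix-loop-helix factors, at -1.73 and -1.51. Aldh1b1, Fbln2 (-1.62), Dusp9 (-1.51), Thy1 (-1.49) and Emid1 (-1.46) were among the falls too. Trend removal over all genes gave Tff2 0.88, Arg1 2.42, Col2a1 -1.01, Id1 -2.38 and Emid1 -0.87, all past the test. The embryonic globin Hbb-y was at -2.22 (adjusted p = 0.0194, and -4.73 after that removal), with -1.46 without control replicate 3, and its call ended without AMI-5 replicate 1 (-2.17), AMI-5 replicate 2 (-2.27) or AMI-5 replicate 3 (-2.16).

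Over all protein-coding genes, the rule of the study's design selected mainly genes with near copies. The values of these are uncertain because reads of a copy can be counted for another or left uncounted, and the settings for such reads are not given. The largest rises were the amylase copies Amy2a4, Amy2a2 and Amy2a3 (log2 fold changes 10.87, 10.56 and 9.24, with 100% of 50-mers shared), Amy2a5 (7.68), the elastase Cela3a (7.29) and the aldolase-like Aldoart1 (7.46). In controls, Amy2a4, Amy2a2, Amy2a3 and Amy2a5 were at means of 0.279, 0.776, 0.420 and 1.73 CPM. Reads exchanged among these amylase copies alone would therefore not give their rises. Without control replicate 2 Amy2a3 was at 10.11, Cela3a at 8.02 and Aldoart2 at 8.70, and without control replicate 3 Aldoart1 was at 8.18 and Rpl36a-ps1 at 9.04. Rpl36a-ps1 and mt-Nd3 had 3 and 2 control reads, and ratios of rates of 308 (95% exact interval 105 to 1490) and 248 (68.5 to 2050). Trend removal gave log2 fold changes of 4.72 instead of 8.14 for Rpl36a-ps1, 4.198 instead of 7.77 for mt-Nd3 and 6.12 for Cela3a. The mitochondrial mt-Co2, mt-Atp6 and mt-Co3 rose by log2 fold changes of 6.93, 6.82 and 6.74 (after trend removal 4.25, 4.11 and 4.38), with 100%, 99.5% and 99.9% of their 50-mers in other genes. Falls included the ribosomal protein genes Rpl35 (-3.14, or -3.78 after trend removal), Rpl21 (-2.34), Rpl9 (-2.28), Rps15a (-1.95) and Rplp2 (-1.87), the nucleolar methyltransferase Fbl (-2.73) and Cntnap4 (-2.18). Rps28 was at -2.63 (adjusted p = 0.0231, and -3.31 after trend removal), a call that ended without control replicate 2 (-2.65), AMI-5 replicate 1 (-2.60), AMI-5 replicate 2 (-2.63) or AMI-5 replicate 3 (-2.61).

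Transcript classes differed between the groups in composition. Of 13 mitochondrial mRNAs, 12 were higher and 1 was lower (camera adjusted p = 3.19e-16, and adjusted p = 0.789 with an estimated correlation). With GC and length trends removed the list had 6 higher and 6 lower (median 0.26 instead of 1.21, adjusted p = 0.373), and mt-Cytb, which shares none of its 50-mers, moved from 0.56 to -0.94 (0.14 over unique-sequence genes, adjusted p = 0.122). Of 85 ribosomal protein genes, 24 were higher (25 adjusted over the list alone) and 38 lower, and of 24 histone cluster genes 4 were higher and 7 lower. Trend removal over all genes gave 13 higher and 56 lower for ribosomal protein genes (camera adjusted p = 3.15e-15) and 2 higher and 17 lower for histone cluster genes (camera adjusted p = 0.000542), so that both lists became calls, as the ribosomal list did without control replicate 3 (adjusted p = 0.0336), without AMI-5 replicate 1 (adjusted p = 0.0478) and with no filter (adjusted p = 0.0233). With an estimated correlation, adjusted p after trend removal was 0.706 for ribosomal protein and 0.685 for histone cluster genes, and before it 0.934 and 0.932. Trend removal over unique-sequence genes called neither list. It gave 1 higher and 1 lower of 5 ribosomal protein genes (camera adjusted p = 0.103, in the other direction) and 0 higher and 1 lower of 4 histone cluster genes (camera adjusted p = 0.604). Of 21 small noncoding RNA genes, 12 were lower and 0 higher (camera adjusted p = 0.00928, and adjusted p = 0.789 with an estimated correlation). Scarna9, a small Cajal body RNA, had 75 control reads and 1 AMI-5 read, a ratio of control over AMI-5 of 129 (95% exact interval 22.4 to 5160). Its log2 fold change of -6.45 became -7.60 with AMI-5 libraries thinned and -7.17 after trend removal. Without AMI-5 replicate 3, which held its only AMI-5 read, it was -7.99, a value that rests on the small count edgeR adds. The transcription regulator Rn7sk was at -2.86, or -5.81 after trend removal. Processed pseudogenes took 0.390% ± 0.0175 of counts in controls and 3.03% ± 0.122 with AMI-5 (SD, n = 3), and their median log2 fold change was 4.46.

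The libraries also differed in general measures. Genes with at least 1 read numbered 22343 to 22738 in controls and 25658 to 26254 with AMI-5, and after thinning to the smallest library 22343 to 22526 and 23952 to 24543. The 50 most abundant genes took 19.4% ± 1.39 and 25.4% ± 1.29 of counts, mitochondrial genes 1.02% ± 0.0699 and 1.64% ± 0.032, and ribosomal protein genes 2.02% ± 0.0976 and 1.52% ± 0.0893 (SD, n = 3). For total counts, genes with a read and these shares, the acinar and pseudogene shares included, the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Histone cluster genes took 0.0260% ± 0.00617 and 0.0227% ± 0.0027 (exact permutation p = 0.5). Across 10915 unique-sequence genes, which are not independent replicates, the log2 fold change fell with GC content, from a median of 0.191 in the lowest of 4 equal classes of GC content to -0.303 in the highest. In these genes it hardly followed gene length (Spearman rho 0.0679, against -0.46 with GC content).

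**Figure D3:**
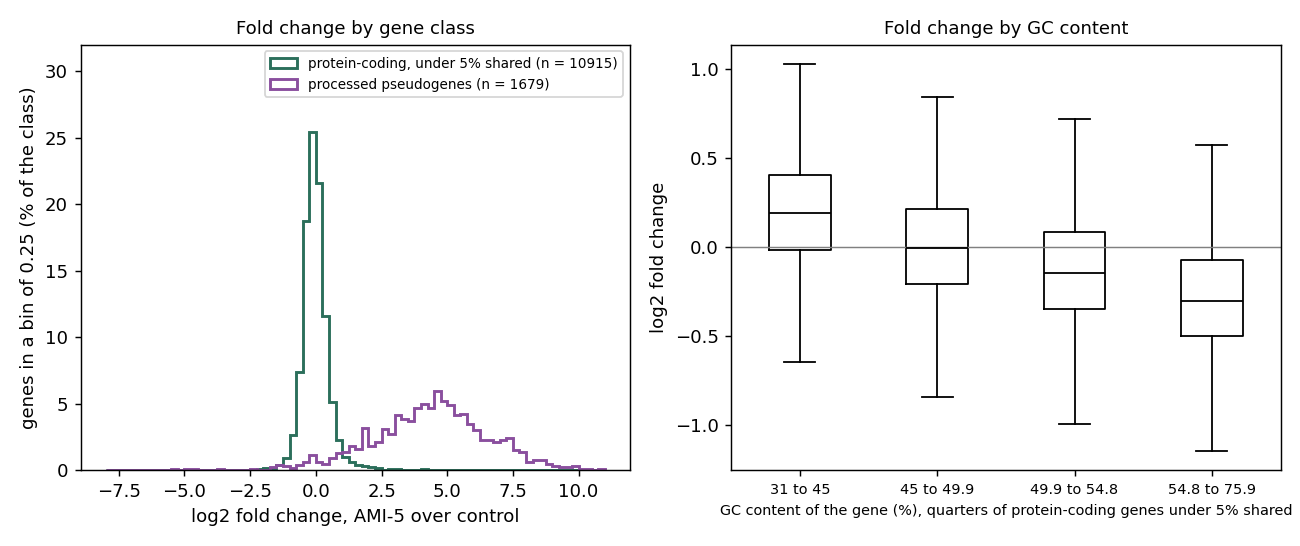
Left, distribution of log2 fold changes of AMI-5 over control (x axis) for 10915 unique-sequence protein-coding genes and 1679 processed pseudogenes. Right, log2 fold change (y axis) by class of GC content (x axis, 4 equal classes) of the unique-sequence genes as box plots, with medians from 0.191 in the lowest to -0.303 in the highest class.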

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

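The fits on unique-sequence genes and on thinned AMI-5 libraries, and estimated correlations after trend removal, were chosen after seeing the data. Under 21 alternatives, 155 named genes gave 3130 comparisons, of which 2950 kept their side of the threshold without a reversal, 146 lost and 16 gained a call and 18 reversed. A reversal is a change of sign where at least 1 of the 2 fits called the gene. Changes of sign in uncalled genes, such as Afp (from -1.20 to 3.62), count among the 2950. Counts of higher and lower genes stayed within 1.5 times except in the test against a fold of 1.5 (2286 and 545) and, with fewer genes tested, over unique-sequence genes (2495 and 2733, or 1646 and 2626 with GC and length trends removed). Of the reported calls, 2759 of 4802 higher and 3167 of 4646 lower recurred with trends removed over all genes, and 1264 of 2143 and 2100 of 3308 over unique-sequence genes. Without each library in turn the counts ranged from 4481 to 4744 and from 3954 to 4316. The replicate block gave 4704 and 4482. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0579, -0.0377 and -0.048 across genes. Of the 11 list calls, 0 held with an estimated correlation (adjusted p = 0.789, or 0.794 for cholesterol), while 20 lists were called with no filter and 22 by fry. Leaving out 1 library brought calls to 7 uncalled lists, Notch among them (adjusted p = 0.0166 without AMI-5 replicate 2). With the strict filter, adjusted p was 0.0748 for multipotent progenitors and 0.0806 for lysine methyltransferases and small noncoding RNAs, with fewer members tested. With GC and length trends removed, adjusted p was 0.0733 for endocrine progenitors (median -0.366 against -0.527, and adjusted p = 0.00124 over unique-sequence genes), 0.154 for multipotent progenitors (median -0.272 against -0.31, and adjusted p = 0.000756 over unique-sequence genes), 0.67 for lysine methyltransferases (median -0.154 against -0.208, adjusted p = 0.404 with the block, 0.154 over unique-sequence genes) and 0.373 for mitochondrial mRNAs (median 0.259 against 1.21, adjusted p = 0.653 with the block, and 0.876 in the other direction over the 4 unique-sequence members). With an estimated correlation as well, 0 lists were called (adjusted p = 0.24 for small noncoding RNAs, 0.685 for mitosis, 0.809 for DNA replication and the stress response, 0.861 for glycolysis, 0.886 for endocrine progenitors and 0.946 for the others), as over unique-sequence genes (0), where adjusted p was 0.384 for mitosis, DNA replication, the stress response, glycolysis and endocrine progenitors, 0.409 for acinar genes, 0.469 for lysine methyltransferases, 0.482 for multipotent progenitors, 0.663 for cholesterol and 0.943 for mitochondrial mRNAs in the other direction. Trend removal turned the log2 fold change of Ins1 to -0.93 (-0.94 with the block), Ctrb1 to -0.46 (-0.46), Lyz2 to -0.12 (-0.11), C1qa to -0.74 (-0.73, but 0.33 and past the test over unique-sequence genes), Lum to -0.079 (-0.075, and 0.17 over unique-sequence genes), Ehmt2 to 0.12 (0.12), mt-Cytb to -0.94 (-0.94) and Riok1 to -0.0017. Col1a1 turned to 0.23 (0.22), and to 0.064 over unique-sequence genes. Where no reason is given, the cause was not tested. Depth limits genes with few control reads most, such as Aldoart2 with 3.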

Other observations

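Tests of source genes, of source genes summed with their copies and of near-identical copies of pseudogenes, and of a single factor for acinar genes, were chosen after the results were seen. Among mesenchyme genes, the matrix proteoglycan Dcn went from 199.6 ± 6.73 to 355 ± 30.7 CPM (SD, n = 3; log2 fold change 0.83, SE 0.068) and the matrix protein Postn from 119 ± 6.76 to 195 ± 24.4 CPM (0.71), while the smooth muscle actin Acta2 went from 40.2 ± 1.89 to 28.5 ± 2.67 CPM (-0.49). With GC and length trends removed over all genes these were at 0.17, 0.36 and -0.90, and passed. Among targets of Nrf2, which controls antioxidant genes, the cystine transporter Slc7a11, which the integrated stress list also holds, was higher (1.31), whereas the thioredoxin reductase Txnrd1, the glutathione transferase Gstm1 and the pentose phosphate enzyme Pgd were lower (-0.51, -0.96 and -0.58; Gstm1 shares 18.9% of its 50-mers).

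For processed pseudogenes, higher in 1576 of 1679 cases, near-identical copies alone were argued against by a median log2 fold change of 4.67 in pseudogenes with under 5% of 50-mers shared, depth by 1382 of 1576 still higher after thinning, and genomic DNA as the whole rise by olfactory and vomeronasal receptor genes 1.45 times as high, under the bound of 2 set in advance, though every AMI-5 library was above every control (13.2 ± 0.619 and 19.1 ± 2.49 CPM, SD, n = 3, exact permutation p = 0.1), so that a smaller part stays open. Reads of source genes placed on diverged copies remain a candidate explanation for part of the rise: 56 source genes of at least 5 copies had a median of -0.227 against -0.0557 in 13605 genes with none (permutation p = 0.009). Summed with their copies, these 56 source genes had a median log2 ratio of 0.639 (quartiles 0.129 and 1.96). Genes with none were at -0.0555 (permutation p = 1e-05). A transfer of counted reads from source to copy would leave such sums unchanged, so for these sums it was argued against as the whole rise. Copies entered only if they passed the filter, which a copy near 0 in controls can pass through AMI-5. Source genes with rising copies were thus preferred, and the result does not cover the others. Across 1633 copies, level and source level correlated at a Spearman rho of 0.171 with AMI-5 (permutation p = 1e-05, like the former the smallest the permutations can give) and 0.0579 in controls (permutation p = 0.02), across genes that are not independent replicates. Read literally, kit and treatment coincide here too, and no biological explanation was tested.

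The rise of acinar genes was not accounted for by shared sequence, since unique-sequence members had a median log2 fold change of 1.17, nor by the GC and length trend as the whole cause, with a median of 1.09 after removal (17 higher and 6 lower of 33). A larger share of unchanged acinar cells would move acinar genes by about 1 factor. With GC and length trends removed over unique-sequence genes, the log2 fold changes of 20 unique-sequence members that no other cell type list holds ran from -0.31 to 4.46. Their SD was 1.41 against a median SE of 0.206, more spread than 1 factor alone would give. Before trend removal, uncalled lists also had an SD above their median SE, such as beta cells (0.811 and 0.0898) and mesenchyme (0.558 and 0.0913), though not interferon (0.568 and 0.834). The spread is thus not particular to acinar genes and does not decide how far a larger share of acinar cells contributed. The library kit, which read literally differs between the groups, cannot be told apart from AMI-5. That 0 title marks are found in both groups adds nothing, since the marks A and Am follow the groups. An effect of AMI-5 stays open and was not tested.

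The falls of mitosis and DNA replication genes and the rise of glycolysis genes were not accounted for by shared sequence or by the GC and length trend. Among the 3 lists, the median nearest to 0 was -0.511 in unique-sequence members and -0.665 after removal of the trends. The library kit or preparation batch, read literally, cannot be told apart from AMI-5. The count of 0 title marks in both groups adds nothing here either. An effect of AMI-5 stays open here too, untested.

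The 6 libraries make 10 splits, too few for a share under 0.05. The real split called 4820 higher and 4652 lower genes, with as many in 1 and 1 of the 10 splits, the real one included, and at most 0 on either side in the others. For list shifts, 9 of the 10 splits, the real one included, called as many lists as the real 11, and the highest other called 20. The other splits mix both groups on each side. The group difference then widens the spread within sides and partly remains between them, so these splits cannot show how many calls would arise without it.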
